A study of Mus musculus with 4 samples.

How the data were processed

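Gastrocnemius muscle RNA of mice aged 6 weeks was measured on 4 Affymetrix expression arrays. Per the labels, 2 arrays hold RNA of non-transgenic littermates and 2 of MCK-PPARb transgenic mice, which overexpress the nuclear receptor PPARbeta (gene Ppard) in muscle. Total RNA was extracted with RNAzol B and labelled as biotinylated cRNA, per the labels' protocols. The labels call the arrays of a group biological replicates, so each array was taken as 1 mouse. The design text can be read otherwise, and p-values then measure only the spread between these samples, which may be technical.

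The deposited values are 1 signal intensity per probe set and array on a linear scale. MAS5 and GCOS are named in the submitters' processing notes, and their versions are not given in the sources used here. The mean signal intensity after leaving out 2% of the deposited probe sets at each end was 1501 on each array, so the arrays had been scaled to a common level. No value was 0 or below, and no column belonged to a sample outside the series. The number of arrays limits the precision.

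Of 22690 probe sets, 64 control probe sets were left out. Of the other 22626, 20380 carried 1 gene symbol in the platform annotation, 691 carried several and 1555 were unnamed here. Symbols were updated through the gene number for 20351 probe sets, using the gene table of assembly GRCm38.p6. No gene was named from a probe set with several symbols.

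Signals were taken as deposited and put on the log2 scale with no pseudocount. Probe sets were kept when their mean log2 signal over all 4 arrays exceeded the median of all probe sets, which lies at 444 signal units. This left 11313 probe sets and 6841 genes. A gene was represented by its probe set of highest mean. The groups were compared with limma 3.58.1 in R 4.3.3, with lmFit and eBayes with an intensity trend, a moderated test in both directions and Benjamini-Hochberg adjustment over the kept probe sets. A probe set or gene is called changed at an adjusted p under 0.05. Differences are MCK-PPARb minus non-transgenic. A fold is the ratio on the scale of the fitted log2 means. The prior added 5.38 degrees of freedom to 2 residual ones.

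Gene lists for muscle metabolism, fibre type, stress and other cell types were written down before the data were examined, together with the tests, the alternatives and the rule for named genes. Lists with at least 5 measured members, 28 in number, were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over the lists. With an estimated correlation, camera works with the 2 residual degrees of freedom. A call can then be lost for want of precision alone. The p of fry tests whether the genes of a list move, on balance, in 1 direction, and does not compare them with other genes. Member counts are given over all probe sets tested and adjusted over the list alone.

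The rule for named genes took Ppard, the 12 genes with the largest called difference in each direction among those whose groups do not overlap, up to 4 members of smallest p in each list, and 15 genes always reported where measured. Further members that passed the adjustment over a list alone, and the genes Mb, Tnnc1, Myh3, Ucp1 and Cidea, were added after their values were seen. The other members of the adipocyte and Schwann cell lists below the filter were also added then. Genes called only in a probe set other than their probe set of highest mean were added after their values were seen as well. A gene with a RIKEN name is given by count.

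The alternatives were quantile normalization, median centring, a pseudocount of 138.7, no filter, a filter at the 75th percentile, eBayes without the trend, robust eBayes, a replicate block, leaving out each array in turn, an adjusted p under 0.1, leaving out probe sets with the suffixes _s_at and _x_at, the mean of a gene's probe sets, and a rule of size without a test. Quantile normalization with a replicate block, quantile normalization with non-transgenic array 1 left out, and signals below the filter level raised to it were added after seeing the data.

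The fit was tested on 20 simulated data sets of 11313 probe sets with 200 changed probe sets each. It recovered 10.1% of changes of 1 on the log2 scale, 70.3% of changes of 2 and 98.0% of changes of 4, and 4.61% of its calls were false. Of 400 unchanged lists, 5 had a p under 0.05 with camera at the preset correlation, and a list of 20 genes shifted by 0.6 was called in 20 of 20 simulations. The simulated genes varied independently, whereas the estimated correlation within the lists measured here reached 0.74, for fast fibre genes. The simulation therefore cannot show that the list test keeps its error rate on lists whose members move together. The simulated arrays also had no deviations shared by many probe sets. The 4.61% of false calls holds for that setting and need not hold for the calls made here.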

Results

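The series asked how overexpression of PPARbeta in skeletal muscle changes the transcripts of the gastrocnemius, a calf muscle made mostly of fast fibres. Signals of 2 non-transgenic and 2 MCK-PPARb arrays were compared. The median signal was 466 and 431 on the non-transgenic arrays and 513 and 454 on the MCK-PPARb arrays. Over the kept probe sets, which are not independent replicates, log2 signals correlated at r = 0.946 within the non-transgenic group, 0.955 within the MCK-PPARb group and 0.924 to 0.946 between groups. Non-transgenic replicate 1 was brighter at the top of the scale: its 10 brightest probe sets held 4.20% of the signal, against 2.36% to 2.78% on the other arrays. The ratio of the 3-prime to the 5-prime control probe set of Gapdh ran from 0.818 to 0.861. That of Actb was 0.481 on non-transgenic replicate 1 and 0.592, 0.579 and 0.558 on non-transgenic replicate 2 and MCK-PPARb replicates 1 and 2.

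Ppard, the overexpressed gene, rose 45.1-fold. Its signal was 2169 and 2825 in non-transgenic muscle and 126049 and 98797 in MCK-PPARb muscle, a log2 difference of 5.49 ± 0.22 (SE, n = 2 per group, adjusted p = 0.000187 with limma). It has 1 probe set on the array, and its direction matches the labels. Sln, which encodes sarcolipin, an inhibitor of the sarcoplasmic reticulum calcium pump, had the largest difference of all called genes, from 268 and 737 to 76835 and 82798 (log2 7.49 ± 0.42, adjusted p = 0.000412). Its non-transgenic signals lie around the filter level of 444 units, so the size is uncertain, and with signals below that level raised to it, an alternative chosen after seeing the data, the difference was 7.12. Igf2, a fetal growth factor, rose 19.3-fold to 85403 and 82189 (log2 4.27 ± 0.18, adjusted p = 0.000187). Actc1, the cardiac alpha-actin gene, had the largest difference among the genes that fell, from 149762 and 69947 to 3228 and 6023 (log2 -4.54 ± 0.41, adjusted p = 0.00562).

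In all, 50 genes were called, 28 higher and 22 lower in MCK-PPARb muscle. Over the kept probe sets, 68 were called, 38 higher and 30 lower, and 55 genes had a called probe set. Dnm2 (log2 2.98), Clu (1.78), Cog4 (1.39), St3gal6 (-1.89) and Tnfrsf21 (-1.85) had one that is not their probe set of highest mean, so they are not among the 50. The ranks below are among the 50 genes. Besides Sln, Ppard and Igf2, the largest rises were those of the heat shock genes Hspa1b (log2 4.83), Hspa1a (4.12) and Dnajb1 (2.79), Atp1b4, a muscle protein related to the beta subunit of the sodium pump (4.31), Enpep, a cell-surface aminopeptidase (3.56), Cdkn1a, which encodes the cell cycle inhibitor p21 (3.52), Rgs2, a regulator of G protein signalling (2.42), Ppp1r1a, an inhibitor of protein phosphatase 1 (2.35), and Acss1, mitochondrial acetyl-CoA synthetase (2.08). Their adjusted p ran from 0.000412 to 0.0166, and both MCK-PPARb arrays lay above both non-transgenic arrays for each. Atp1b4 read 123 and 88.8 and Enpep 250 and 589 in non-transgenic muscle, so their sizes and ranks are uncertain, and with signals raised to the filter level their differences were 2.22 and 3.15. The other 16 genes that rose had log2 differences of 1.17 to 1.85.

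Besides Actc1, the largest falls were those of Smox, which encodes spermine oxidase (log2 -3.96), Ighm, the immunoglobulin mu heavy chain (-3.96), the tetraspanin Tspan8 (-2.83), Tiam1, a Rac exchange factor (-2.82), the surface glycoprotein Cd24a (-2.44), Padi2, a peptidylarginine deiminase (-2.23), Gpd2, mitochondrial glycerol-3-phosphate dehydrogenase (-2.22), Phkb, the beta subunit of phosphorylase kinase (-2.14), Tmem37 (-1.98) and Prxl2b (-1.81). In MCK-PPARb muscle Ighm read 196 and 214, Tiam1 297 and 179 and Tspan8 361 and 487, below or around the filter level, so their sizes and ranks are uncertain. With signals raised to that level the differences were -2.84 for Ighm, -2.68 for Tspan8 and -1.88 for Tiam1, which then did not pass (adjusted p = 0.0816). Another kept probe set of Ighm had the opposite sign, and with the mean of a gene's probe sets Ighm was at -1.40 and did not pass (adjusted p = 0.338), while Tspan8 was at -1.89. In this group 1 further gene has a RIKEN name. Their adjusted p ran from 0.000412 to 0.0471. The other 10 genes that fell had log2 differences of -1.62 to -1.15. The groups did not overlap for any of the 68 called probe sets, while 41.1% of all kept probe sets did not overlap and chance gives 33.3%. An exact permutation test of a single gene cannot go below p = 0.333 with 2 arrays against 2, so all calls rest on the spread that limma pools over genes. Without MCK-PPARb replicate 1 or 2, 26 and 31 genes were called, 22 and 25 of them among the 50, and without non-transgenic replicate 1 or 2, 91 and 105 genes, 48 and 48 of them among the 50; without the intensity trend 14 were called.

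**Figure D1:**
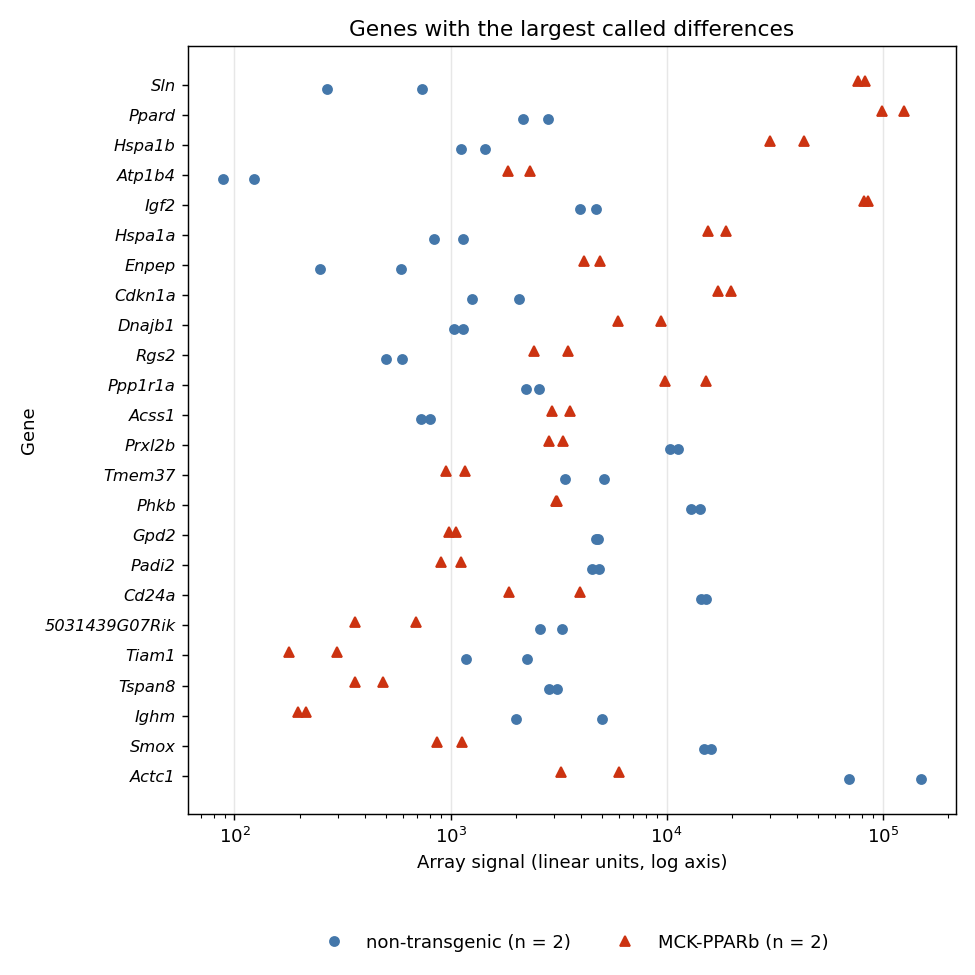
Signal of each array (linear units on a log axis) for the 12 genes with the largest called rise and the 12 with the largest called fall, with 1 point per array, circles for non-transgenic and triangles for MCK-PPARb muscle. Sln lies at 268 and 737 in non-transgenic and at 76835 and 82798 in MCK-PPARb muscle, and Actc1 runs the other way.

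Members of the fixed lists passed 76 times when adjusted over their list alone. Leaving out an array cannot turn the direction of a member whose groups do not overlap. Dropping the intensity trend leaves every difference as it was. Of these calls, 68 and 71 held without non-transgenic replicate 1 or 2, 41 and 30 without MCK-PPARb replicate 1 or 2, and 45 without the intensity trend, and all 76 kept their direction in these 5 alternatives. Without MCK-PPARb replicate 2, none held in the lists of PPAR targets, fatty acid uptake, peroxisomal oxidation, the citric acid cycle, glucose uptake, fast fibres, metabolic regulators, branched-chain amino acids, antioxidants, immediate early genes and Schwann cells. Without MCK-PPARb replicate 1, none held in the same lists apart from PPAR targets, immediate early genes and Schwann cells.

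Genes typical of slow fibres rose as a list, with a median log2 difference of 0.77 (camera, adjusted p = 8.83e-10). The call was lost at adjusted p = 0.455 with an estimated correlation, in a range of 4.96e-20 to 0.455 over the alternatives. The median was 0.45 without non-transgenic replicate 1 and 0.45 to 0.93 over the alternatives. Of 19 measured members, 2 rose, 0 fell and 17 did not pass over all genes, and 11 rose and 1 fell when adjusted over the list alone. Over all genes, Sln and the small heat shock gene Hspb7 (log2 1.48 ± 0.23) passed. Myl2, the slow myosin light chain (2.83-fold, adjusted p = 0.0540), and Casq2, the calsequestrin of slow and cardiac muscle (1.60 ± 0.27, adjusted p = 0.0650), rose when adjusted over the list alone, as did Tnnc1, slow troponin C (1.13). Mb, which encodes myoglobin, fell by 0.53 on the log2 scale when adjusted over the list alone. Myh7, the slow myosin heavy chain, read 7612 and 17024 in non-transgenic and 17671 and 18456 in MCK-PPARb muscle and did not pass (log2 0.67 ± 0.35, adjusted p = 0.563). Markers of adipocytes and of Schwann cells and nerve moved the same way, with medians of 0.70 and 0.61, as did immediate early genes (0.52).

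Genes typical of fast fibres had a median log2 difference of -0.32, and the list fell (camera, adjusted p = 0.00137). The call was lost at adjusted p = 0.673 with an estimated correlation and at 0.103 with quantile normalization, where the median was -0.072. None of its 20 measured members passed over all genes, 2 had an unadjusted p under 0.05 in limma, and 0 rose and 1 fell when adjusted over the list alone. Adipocyte (0.70) and Schwann cell markers (0.61) moved the other way. The gene that fell was Gpd1, cytosolic glycerol-3-phosphate dehydrogenase (-0.95 ± 0.18). Differences were -0.78 for Mylk2, -0.58 for Pygm, -0.47 for Myl1 and -0.22 ± 0.28 for Myh4, the main fast myosin heavy chain, whose sign turned with quantile normalization (0.094). Without non-transgenic replicate 1, the array brighter at the top, the median was 0.073 and the adjusted p 0.901, and -0.076 and 0.104 with quantile normalization as well, chosen after seeing the data. Without non-transgenic replicate 2 the median was -0.79, and without MCK-PPARb replicate 2 the adjusted p was 0.0638, in a range of 1.02e-15 to 0.901 over the alternatives.

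Genes of mitochondrial fatty acid oxidation rose as a list, with a median log2 difference of 0.15 (camera, adjusted p = 0.00238). The call was lost at adjusted p = 0.455 with an estimated correlation, in a range of 0.000389 to 0.455 over the alternatives. Of 22 measured members, 1 rose, 0 fell and 21 did not pass over all genes, and 4 rose and 0 fell when adjusted over the list alone. Etfdh, which passes electrons from fatty acid oxidation to ubiquinone, rose 2.37-fold (log2 1.25 ± 0.19, adjusted p = 0.0431). Adjusted over the list alone, Hadha (0.76 ± 0.17) and Acadl (0.90 ± 0.22), enzymes of beta-oxidation, and Acat1, a mitochondrial thiolase (0.76 ± 0.20), rose as well. Adipocyte markers (median 0.70), Schwann cell markers (0.61) and immediate early genes (0.52) moved the same way.

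The list of PPAR target genes rose, with a median log2 difference of 0.15 (camera, adjusted p = 0.0250). The call was lost at adjusted p = 0.455 with an estimated correlation, and at 0.0604 without MCK-PPARb replicate 1, in a range of 0.00179 to 0.455 over the alternatives. The median was 0.26 without non-transgenic replicate 1, 0.29 without MCK-PPARb replicate 2, 0.27 with the mean of a gene's probe sets and 0.10 to 0.29 over the alternatives. None of its 30 measured members passed over all genes, and 11 had an unadjusted p under 0.05 in limma. When adjusted over the list alone, 7 rose and 2 fell. Pdk4, the kinase that restrains pyruvate dehydrogenase, rose from 18338 and 20094 to 40918 and 37141 (log2 1.02 ± 0.18, 2.03-fold) in that adjustment, with an adjusted p of 0.0699 over all genes. The others that rose in that adjustment were the fatty acid binding protein gene Fabp3 (0.98 ± 0.18), the catalase gene Cat (1.08 ± 0.21), Hadha, Acadl, Txnip (0.73) and the fatty acid transporter gene Cd36 (0.70, and 0.46 without MCK-PPARb replicate 1). Tfrc, the transferrin receptor (-1.35 ± 0.23), and Gpd1 fell. Ucp3 had a difference of -0.43 ± 0.35 and did not pass. Angptl4 lay below the filter, at 303 and 66.9 in non-transgenic and 953 and 941 in MCK-PPARb muscle, and its other probe set, also below the filter, read 159 and 97.5 against 55.6 and 5.40. Fabp3, Cd36 and other members are also expressed in fat, whose markers had a median of 0.70, while Schwann cell markers were at 0.61 and immediate early genes at 0.52. These medians do not show how much fat added to the signals of Fabp3 or Cd36, which was not tested.

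The lists of fatty acid uptake and peroxisomal oxidation were not called (camera, adjusted p = 0.204 and 0.628). Of their 19 and 15 measured members, none passed over all genes, with an unadjusted p under 0.05 in limma for 4 and 5. When adjusted over the list alone, 1 rose in each, Fabp3 in the former and Cat in the latter. Among the next members, differences were 0.70 for Cd36, -0.60 for Vldlr and -0.56 for Dbi, which had another kept probe set of the opposite sign, and 0.69 for Eci2, -0.80 for Scp2 and -0.72 for Abcd2. Of 18 measured genes of triglyceride and fatty acid synthesis, 1 rose over all genes, Scd1, the stearoyl-CoA desaturase (1.49 ± 0.21, adjusted p = 0.0348). When adjusted over the list alone, 3 rose, Scd1, Fasn (1.60) and Dgat2 (0.96), and 2 fell, the lipogenic regulator Srebf1 (-1.13) and Me1 (-0.95), and the list was not called (camera, adjusted p = 0.204). Scd1 is also on the list of adipocyte markers, which had a median of 0.70, with Adipoq at 1.03 and Retn at 1.02.

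Glycolytic genes fell as a list, with a median log2 difference of -0.35 (camera, adjusted p = 0.00133). The call was lost at adjusted p = 0.561 with an estimated correlation, and at 0.0684 without non-transgenic replicate 1, the array brighter at the top, in a range of 3.16e-07 to 0.561 over the alternatives. The median was -0.21 with quantile normalization, -0.11 without non-transgenic replicate 1, -0.61 without non-transgenic replicate 2 and -0.61 to -0.11 over the alternatives. With quantile normalization and non-transgenic array 1 left out, chosen after seeing the data, it was -0.23 and the list passed (adjusted p = 0.00721). Of 18 measured members, 0 rose, 1 fell and 17 did not pass over all genes, and 0 rose and 3 fell when adjusted over the list alone. Gpd2 fell 4.65-fold over all genes (log2 -2.22 ± 0.21, adjusted p = 0.00705). Slc16a3, a lactate exporter (-0.99 ± 0.19), and Gpd1 fell when adjusted over the list alone. Gpd1 and Gpd2 belong to the glycerol phosphate shuttle rather than to the main glycolytic chain. Pgk1 (-0.59 ± 0.25) and Hk2 (-0.27 ± 0.17), which encode phosphoglycerate kinase and hexokinase 2, did not pass. Fast fibre genes, whose list shares members with this one, moved the same way (-0.32), and adipocyte (0.70) and Schwann cell markers (0.61) the other way.

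Genes of glycogen metabolism fell as a list, with a median log2 difference of -0.20 (camera, adjusted p = 0.00342). The call was lost at adjusted p = 0.455 with an estimated correlation, in a range of 0.000847 to 0.455 over the alternatives. The median was -0.40 without non-transgenic replicate 2, -0.33 without MCK-PPARb replicate 2 and -0.40 to -0.14 over the alternatives. Subunits of phosphorylase kinase, the enzyme that activates glycogen breakdown, were among the members that fell. Phkb fell from 12954 and 14289 to 3071 and 3093 (log2 -2.14 ± 0.18, adjusted p = 0.00433), and the alpha subunit gene Phka1 fell by 1.39 ± 0.17 on the log2 scale (adjusted p = 0.0199). Phkg1, the gamma subunit (-1.37 ± 0.24, adjusted p = 0.0691), fell when adjusted over the list alone. Ppp1r1a rose 5.11-fold. Of 17 measured members, 1 rose, 2 fell and 14 did not pass over all genes, and 2 rose and 4 fell when adjusted over the list alone, with Stbd1 (1.08) and Pgm1 (-0.67) added there. Gys1, muscle glycogen synthase, had a difference of -0.25 ± 0.19 and did not pass. Fast fibre genes, whose list shares Pygm with this one, moved the same way (-0.32), and adipocyte (0.70) and Schwann cell markers (0.61) the other way.

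Genes of glucose uptake and pyruvate use were not called as a list (camera, adjusted p = 0.776, median 0.0060), and the median ran from -0.086 to 0.060 over the alternatives. None of its 21 measured members passed over all genes, with an unadjusted p under 0.05 in limma for 7, while 2 rose and 2 fell when adjusted over the list alone. Pdk4 and Ldhb, the heart-type lactate dehydrogenase subunit (0.78 ± 0.21), rose in that adjustment, and Slc16a3 and Irs1, an insulin receptor substrate (-1.26 ± 0.34), fell. Irs1 read 9321 and 20112 in non-transgenic and 5168 and 6296 in MCK-PPARb muscle, and without non-transgenic replicate 2 its difference was -0.71 and did not pass (adjusted p = 0.0506 over the list alone). Slc2a4, which encodes the insulin-responsive glucose transporter, read 22821 and 25411 in non-transgenic and 20029 and 23430 in MCK-PPARb muscle (-0.15 ± 0.18, adjusted p = 0.833).

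**Figure D2:**
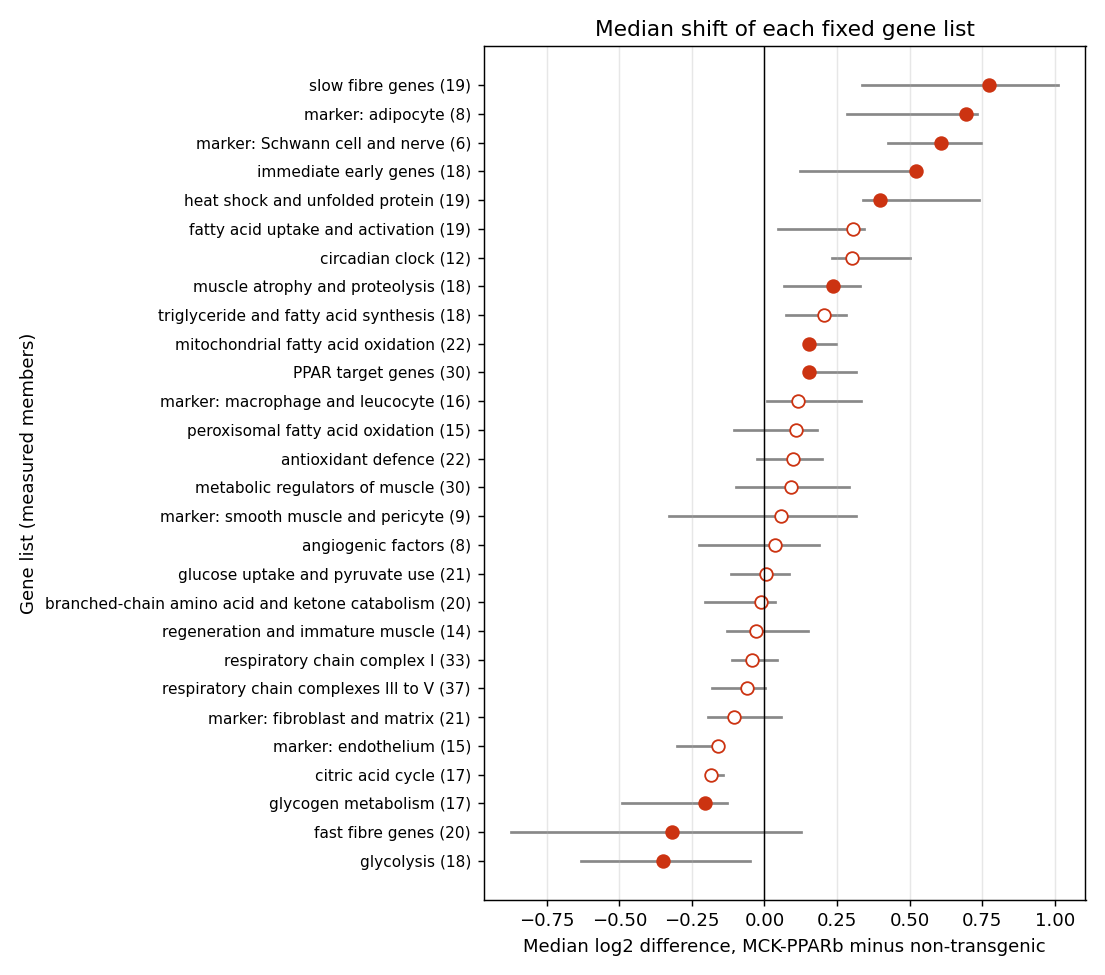
Median log2 difference (MCK-PPARb minus non-transgenic) of each of the 28 tested gene lists, with the number of measured members in brackets. Filled points are lists called by camera with a preset correlation, open points are the others, and grey lines span the medians of the 4 pairs of a transgenic with a non-transgenic array; slow fibre genes lie highest at 0.77 and glycolysis lowest at -0.35, and the line of fast fibre genes crosses 0.

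Heat shock and unfolded protein genes rose as a list, with a median log2 difference of 0.40 (camera, adjusted p = 4.79e-05; fry, adjusted p = 0.000677). The camera call was lost at adjusted p = 0.455 with an estimated correlation, in a range of 1.53e-11 to 0.455 over the alternatives. The median was 0.24 without _s_at and _x_at probe sets and 0.24 to 0.55 over the alternatives. Of 19 measured members, 4 rose, 0 fell and 15 did not pass over all genes, and 8 rose and 1 fell when adjusted over the list alone. Hspa1b rose from 1443 and 1113 to 29981 and 43325 (log2 4.83 ± 0.24, 28.4-fold) and Hspa1a 17.4-fold (4.12 ± 0.23). These 2 genes are near-identical copies, so it is uncertain which of them the probe sets measured. Dnajb1, a co-chaperone, rose 6.92-fold, and Hspb7 rose 2.78-fold. The small heat shock genes Cryab (0.94) and Hspb1 (0.95) rose when adjusted over the list alone, and the stress regulator Atf4 fell (-1.15, and -0.76 without non-transgenic replicate 2). Immediate early genes moved the same way, with a median of 0.52, as did adipocyte (0.70) and Schwann cell markers (0.61).

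Immediate early genes, which respond within an hour to handling, rose as a list with a median of 0.52 (camera, adjusted p = 0.0309), with adjusted p = 0.455 with an estimated correlation. None of its 18 measured members passed over all genes, with an unadjusted p under 0.05 in limma for 4, and 3 rose and 1 fell when adjusted over the list alone. These were Atf3 (2.19 ± 0.60), Jund (0.84) and Jun (0.83), which rose, and Nr4a1 (-1.23 ± 0.21), which fell. Atf3 read 800 and 208 in non-transgenic and 2304 and 1492 in MCK-PPARb muscle, below the filter level on 1 array, so its size is uncertain, and without non-transgenic replicate 2 its difference was 1.21. The adjusted p was 0.0684 without non-transgenic replicate 1 and 0.0771 without MCK-PPARb replicate 1, in a range of 0.00263 to 0.649 over the alternatives. The median was 0.33 with no filter, 0.20 with the filter at the 75th percentile, 0.16 without non-transgenic replicate 1 and 0.035 to 0.60 over the alternatives, lowest with quantile normalization and non-transgenic array 1 left out (adjusted p = 0.0887). Adipocyte (0.70) and Schwann cell markers (0.61) moved the same way.

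The list of muscle atrophy and proteolysis rose (median 0.24, camera, adjusted p = 0.0313), with adjusted p = 0.455 with an estimated correlation, 0.0985 without MCK-PPARb replicate 2, where the median was 0.13, and a range of 0.00549 to 0.455 over the alternatives. Of 18 measured members, 1 rose and 17 did not pass over all genes, and 1 rose and 0 fell when adjusted over the list alone. That gene was Cdkn1a, which rose 11.5-fold and is a growth arrest gene rather than a protease. Bnip3 (0.61), Cebpd (0.81) and Psmd4 (0.30) did not pass. Adipocyte markers (0.70), Schwann cell markers (0.61) and immediate early genes (0.52) moved the same way. The list of regeneration and immature muscle was not called (camera, adjusted p = 0.490), and its mean and median differed in sign, at 0.14 and -0.03, with medians of -0.21 to 0.16 over the alternatives. Of its 14 measured members, Igf2 rose, Actc1 fell and 12 did not pass over all genes. When adjusted over the list alone, 2 rose and 1 fell, with Chrna1, the acetylcholine receptor alpha subunit, added (1.31 ± 0.22). Myh8, the perinatal myosin heavy chain (1.19 ± 0.39), did not pass. Myh3, the embryonic myosin heavy chain, lay below the filter, at 59.9 and 183 in non-transgenic and 1201 and 1561 in MCK-PPARb muscle, and did not pass with no filter (adjusted p = 0.0631).

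The lists of the citric acid cycle and the respiratory chain were not called. Camera gave an adjusted p of 0.0518 for 17 citric acid cycle genes, 0.491 for 33 genes of respiratory complex I and 0.251 for 37 genes of complexes III to V, with medians of -0.19, -0.04 and -0.06. The latter 2 medians had no stable sign, with ranges of -0.12 to 0.027 and -0.11 to 0.040 over the alternatives, highest without MCK-PPARb replicate 1. No member of these 3 lists passed over all genes, and an unadjusted p under 0.05 in limma was seen for 3, 3 and 1 of them. Idh2, mitochondrial isocitrate dehydrogenase (0.87 ± 0.20), was the 1 member that rose when adjusted over the list alone, and 0 members fell in that adjustment. Differences were -0.50 for Sdhd, -0.47 for Idh3a, -0.36 for Idh3g, -0.59 for Ndufc2, -0.81 for Ndufa5, 0.42 for Ndufb7, -0.32 for Ndufv3, -0.91 for Uqcrh, -0.41 for Cox7a1, 0.36 for Cox6a1 and -0.51 for Uqcrb. The citric acid cycle list passed in 7 of 20 alternatives, among them quantile normalization (adjusted p = 0.0371) and the set without non-transgenic replicate 1 (0.0293), in a range of 0.0145 to 0.524.

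Metabolic regulators of muscle were not called as a list (camera, adjusted p = 0.628). None of its 30 measured members passed over all genes, with an unadjusted p under 0.05 in limma for 4, and 0 rose and 1 fell when adjusted over the list alone, the orphan receptor gene Nr4a1. Mef2d (0.70), Rcan1 (-0.67), Mef2a (0.29 ± 0.19), Ppara (0.98 ± 0.38) and the coactivator gene Ppargc1a (-0.06 ± 0.21) did not pass, and other kept probe sets of Ppargc1a had the opposite sign. Branched-chain amino acid and ketone genes were not called (camera, adjusted p = 0.726). Of their 20 measured members, none passed over all genes, with an unadjusted p under 0.05 in limma for 4. When adjusted over the list alone, 3 rose and 0 fell, Bckdha (0.97), Bdh1 (1.01) and Acat1. Oxct1 was at -0.46, and its other kept probe sets differed widely, at -1.33, -0.38 and -0.002. Of 22 measured antioxidant genes, none passed over all genes, 2 had an unadjusted p under 0.05 in limma, and 2 rose and 0 fell when adjusted over the list alone, Cat and Gpx3 (0.81); camera gave an adjusted p of 0.204, and 0.0499 without non-transgenic replicate 1, in a range of 0.0145 to 0.673. Gsta4 (0.49) and Gsr (0.39) did not pass.

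Angiogenic factors and clock genes were not called (camera, adjusted p = 0.905 and 0.251). None of their 8 and 12 measured members passed over all genes, with an unadjusted p under 0.05 in limma for 2 and 3, and 0 rose or fell when adjusted over the list alone. Differences were 0.75 for Hif1a, -0.57 for Egln3, -0.51 ± 0.30 for the vascular growth factor gene Vegfa, 0.33 for Fgf1, -0.60 for Nr1d2, -0.72 for Per1, 1.02 for Nfil3 and 1.10 for Clock, which had another kept probe set of the opposite sign. Of the AMP-activated protein kinase list, 4 members were measured, too few for the list test, with Prkab1 at -0.59, Cab39 at -0.18 and Prkag1 at 0.18, each with a kept probe set of the opposite sign, and Stk11 at -0.041. Cpt1b and Prkag3 were not analysed here.

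Adipocyte markers rose as a list, with a median of 0.70 (camera, adjusted p = 0.0313) and adjusted p = 0.455 with an estimated correlation. Of 8 measured members, 1 rose over all genes, Scd1, and 3 rose and 1 fell when adjusted over the list alone. The fat hormone genes Adipoq (1.03 ± 0.26) and Retn (1.02 ± 0.27) were the others that rose, and Car3, a carbonic anhydrase also abundant in slow fibres, fell (-1.46 ± 0.28). Ucp1 and Cidea, genes typical of brown fat, lay below the filter, at 59.1 and 28.9 against 391 and 447 and at 183 and 117 against 593 and 737, and did not pass with no filter (adjusted p = 0.292 and 0.293). The other members below the filter did not rise in this way. Lep read 131 and 86.8 against 55.7 and 67.2, Pparg 50.1 and 117.5 against 51 and 42.5, and Cidec 196.5 and 203 against 61.3 and 339.9. The adjusted p of the adipocyte list was 0.0974 without non-transgenic replicate 1 and 0.179 without MCK-PPARb replicate 1, where the median was 0.45, in a range of 0.00652 to 0.455. Markers of Schwann cells and nerve rose as a list, with a median of 0.61 over 6 measured members (camera, adjusted p = 0.00235), and had adjusted p = 0.455 with an estimated correlation and a range of 0.00197 to 0.455. None of the 6 passed over all genes, with an unadjusted p under 0.05 in limma for 3. The myelin genes Mbp (0.96 ± 0.18) and Pmp22 (0.67 ± 0.21) rose when adjusted over the list alone, and Cnp (0.59) and Mal (0.63) did not pass. A further 6 members lay below the filter. Both MCK-PPARb arrays read above both non-transgenic arrays for Egr2 and Gjb1 and below them for Mag, Nefl and Nefm, while S100b was mixed.

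Other cell type markers were not called. Camera gave an adjusted p of 0.204 for 15 endothelial, 0.231 for 16 leucocyte, 0.350 for 21 fibroblast and 0.755 for 9 smooth muscle markers. None of these members passed over all genes or rose or fell when adjusted over the list alone, and an unadjusted p under 0.05 in limma was seen for 0, 2, 0 and 1 of them. Differences were -0.52 for Emcn, -0.38 for Esam, -0.33 for Cldn5 and -0.23 for Cdh5, and 0.72 for Cd74, 0.83 for Adgre1, -0.42 for C1qc and 0.56 for Cd14. Those of the fibroblast and smooth muscle lists were 0.45 for Fn1, -0.28 for Col6a3, -0.35 for Thy1, -0.49 for Lum, 0.54 for Smtn, 0.50 for Cspg4, -0.66 for Myh11 and 0.51 for Pdgfrb, which had another kept probe set of the opposite sign. Red blood cell genes Alas2 (0.17) and Hbb-b2 (-0.01) and the Y-linked genes Eif2s3y (-0.40) and Uty (-0.10) were within the spread between arrays. Of the 28 lists tested, 11 were called by camera with a preset correlation, and 0 hold with an estimated correlation. There, 1 list, heat shock, had an unadjusted p under 0.05 (camera, 0.0371), and fry called 1 list, heat shock. The estimated correlation was 0.74 for fast fibre, 0.42 for slow fibre and 0.26 for glycolytic genes. It was negative for heat shock genes (-0.056), PPAR targets (-0.029) and Schwann cell markers (-0.14), whose calls were lost as well. A lost call therefore does not by itself show that members move together.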

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

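Quantile normalization with a replicate block, quantile normalization with non-transgenic array 1 left out and raising signals below 444 units to that level were chosen after seeing the data; the other alternatives were planned. Of the 50 called genes, 50 kept their direction in each alternative that tested 50, as did 42 of 42 with the filter at the 75th percentile and 47 of 47 without _s_at and _x_at probe sets. For most alternatives this was fixed in advance. The groups of a called gene do not overlap, so leaving out an array cannot turn its sign. Changes of the filter, trend, robust setting, threshold or block leave the difference itself as it was. The counts of 68 probe sets (38 higher, 30 lower), 50 genes (28 higher, 22 lower) and 11 lists stayed within 1.5 times with quantile normalization, median centring, a pseudocount, no filter, robust eBayes, no _s_at or _x_at probe sets, the mean of a gene's probe sets, raised signals (77 probe sets, 54 genes, 11 lists) and quantile normalization with non-transgenic array 1 left out (86, 58 and 10, with 37 of the 50 genes kept). The lists fell to 7 with the filter at the 75th percentile, which tests fewer genes, to 0 for camera with an estimated correlation and to 1 for fry. Without the trend, 21 probe sets (13 higher, 8 lower) and 14 genes (8 higher, 6 lower) were called. At an adjusted p under 0.1, by construction a looser limit, 150 probe sets (81 higher, 69 lower) and 102 genes (58 higher, 44 lower) were called. The rule of size, which has no test, took 1417 probe sets (768 higher, 649 lower). Leaving out each array in turn gave 36 to 159 probe sets (18 to 96 higher, 18 to 63 lower), 26 to 105 genes (13 to 59 higher, 13 to 46 lower) and 8 to 11 lists; the lone array of a group is then assumed to vary like the other group.

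Arrays of the 2 groups share replicate numbers, and the labels do not state whether a number marks a shared litter or day. Deviations of same-numbered arrays from their group means correlated at 0.276 across probe sets. With a replicate block, 377 probe sets (209 higher, 168 lower), 218 genes (120 higher, 98 lower) and 11 lists were called, and with quantile normalization as well 427 probe sets (233 higher, 194 lower), 252 genes (138 higher, 114 lower) and 9 lists.

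Among 146 genes, 24 values changed sign, all of genes that were not called. A called gene could not change sign when an array was left out, as its groups do not overlap. The 146 are the genes named for a probe set of highest mean that passed the filter, and 1 with a RIKEN name. Myh4 was at 0.094 with quantile normalization, with or without the block, and with the mean of a gene's probe sets Prkab1 was at 0.76 and Pdgfrb at -0.055. With quantile normalization and non-transgenic array 1 left out, Ucp3 was at 0.10, Myh4 at 0.016, Hbb-b2 at 0.22, Uty at 0.15, Stk11 at 0.27 and Pdgfrb at -0.27. Leaving out each array in turn gave -0.977 to 0.11 for Ucp3, -0.60 to 0.16 for Myh4, -0.15 to 0.039 for Ppargc1a, -0.071 to 1.08 for Cspg4, -0.10 to 0.44 for Alas2, -0.30 to 0.28 for Hbb-b2, -0.85 to 0.045 for Eif2s3y, -0.46 to 0.26 for Uty, -0.37 to 0.29 for Stk11, -1.56 to 0.24 for Myh11 and -0.22 to 1.25 for Pdgfrb. The median of fast fibre genes ran from -0.79 to 0.073 in the same way. Of the other gene values, 2352 stayed on their side of the threshold in the same direction, 52 were no longer past it and 166 newly passed; of the list values these were 508, 40 and 9. Counts of members that passed when adjusted over their list alone stayed within 1.5 times in 978 values and moved further in 138. Lists called in neither setting count as the same whatever their sign. Apart from the points stated by construction, the cause was not tested. Probe sets near or below 444 signal units limit what can be said of dim genes.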

Other observations

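The test on cross-hybridization, the count of pairs without Ppard and Hspa1b, the genes Cdkn1c, Odc1, Kcnc4, Pkdcc, Prepl and Gpcpd1, and the probe sets without a single gene symbol, were chosen only after their values were seen; the other tests were written down first.

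Further genes outside the fixed lists stood out. Odc1, which encodes ornithine decarboxylase, the first enzyme of polyamine synthesis, read 15955 and 10174 in non-transgenic and 5343 and 5593 in MCK-PPARb muscle, a log2 difference of -1.22 that did not pass (adjusted p = 0.0993, limma), beside the called fall of the spermine oxidase gene Smox (-3.96). Cdkn1c, a cell cycle inhibitor gene expressed from the maternal allele, rose 3.29-fold (log2 1.72, adjusted p = 0.0299) and lies 5 measured genes from Igf2, which is expressed from the paternal allele. Kcnc4, a potassium channel gene, lay below the filter. Its probe sets read 1152 and 889 against 56.6 and 62.0, and 2766 and 1076 against 120 and 63.6, in non-transgenic and MCK-PPARb muscle, and passed with no filter (adjusted p = 0.0431 and 0.0305).

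Of the 68 called probe sets, 4 have no single gene symbol. The probe set 1448484_at read 70969 and 58780 in non-transgenic and 4067 and 5556 in MCK-PPARb muscle, and 1416835_s_at read 88508 and 49967 against 3611 and 3801. Their log2 differences were -3.76 and -4.17. The probe sets 1418665_at and 1451716_at rose by 2.58 and 2.41 on the log2 scale.

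Hspa1a, Hspa1b and Dnajb1 were higher in MCK-PPARb muscle. Cross-hybridization between Hspa1a and Hspa1b cannot be told apart from a rise of both, because the smallest difference among their 4 probe sets was 4.12. Slower or rougher handling of the transgenic muscle may also have raised heat shock genes: the median of the immediate early list was 0.12 to 0.54 in the 4 pairs of a transgenic with a non-transgenic array, on both sides of the 0.25 set in advance, so handling stays open. An effect of the transgene stays open as well.

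Sln and Myl2 were higher in MCK-PPARb muscle, and slow muscle included in the transgenic dissection was considered as a source. The median of 7 other slow contractile genes was 0.31 to 0.71 of the difference of Myl2 in the 4 pairs of arrays, on both sides of the 0.5 set in advance. For Myl2 and these genes the dissection therefore cannot be told apart from a change of fibre genes by the transgene. Mb fell by 0.53 on the log2 scale, while Sln rose by 7.49, or by 7.12 with signals below the filter level raised to it, chosen after seeing the data. Car3, also abundant in slow fibres and set beside them after its value was seen, had differences of -1.46 and, in its other probe set, -1.99. Added slow muscle alone would not give the falls of Mb and Car3. In the slow fibre list, 11 members rose and 1 fell when adjusted over the list alone.

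The called genes may also reflect a linked stretch of another strain's chromosome, carried along with the transgene. Among the 50 called genes, 6 pairs lay within 10 measured genes of each other, against a mean of 3.56 in 10000 random draws, and a share of 0.146 of the draws had as many or more. The pairs are Hspa1a with Hspa1b, Igf2 with Cdkn1c, Ppard with Cdkn1a, Pkdcc with Prepl, Smox with Gpcpd1 and Padi2 with Hspb7, and the other 38 called genes lie in none. Ppard is the overexpressed gene and Hspa1a and Hspa1b are near-identical copies; without Ppard and Hspa1b, 4 pairs remained, against a mean of 3.23 in the draws, with a share of 0.401. A single short stretch would place the called genes near each other. The 38 called genes in no pair argue against it as the source of all 50 called genes, though not of some of them. The number of pairs lay between the limits set in advance, so that count decided neither way. A stretch much longer than 10 measured genes was not tested. For genes within a pair, such a stretch and an effect of the transgene cannot be told apart.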
